A study of Mus musculus with 44 samples.

How the data were processed

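RNA was measured on 44 single-channel Illumina mouse BeadChip arrays, each carrying 45281 probes. Per the labels, the total RNA came from meiotic cells (spermatocytes) and postmeiotic cells (round spermatids) of adult mouse testes, in 2 experiments. Experiment 1 compared wild-type mice with mice that carried a tagged allele of TH2B, the testis histone H2B, with 6 arrays for each genotype and cell type (24 arrays). Experiment 2 compared wild-type mice with mice labelled kd, which the labels describe as lacking TH2B, with 5 arrays for each genotype and cell type (20 arrays). The genotype field of the labels names another gene (brdt), and the genotypes were therefore taken from the array titles and the study design. How the cells were purified is not given in the sources used here.

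The deposited raw file gives, per the file headers, the mean bead intensity of each probe on each array, with no normalization visible in the values. The same deposited file gives a detection p value per probe and array, in steps of 1 in 936, which compares the probe with negative control beads. The deposited processed file also holds an intensity per probe and array. In its values the authors had quantile normalized all 44 arrays on the linear scale without subtracting background, as shown by array medians between 104.3 and 104.4 and by probe ranks identical to those of the raw intensities. The software used for this step is not given in the sources used here. Median raw intensities ran from 91.4 to 119 across arrays, and between 15997 and 19348 probes per array were above background at a detection p under 0.05. These signals over background, and the number of arrays, limit the precision.

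The raw intensities were processed with limma 3.58.1 in R 4.3.3. Background was corrected with the normexp model using detection p values, an offset of 16 was added, and the arrays were quantile normalized and put on the log2 scale (function neqc). Probes with a detection p under 0.05 in at least 5 arrays were kept (22605 probes). Of these, 18813 had a gene name and 3792 did not. Each of 12260 genes was represented by the kept probe with the highest mean over all arrays. Gene symbols were current ones, chromosomes were those of the GRCm38.p6 annotation, and 706 of the 707 symbols in the fixed gene lists were matched. Probes of near-identical gene copies, among them the clustered histone genes, Chil3 and Chil4, Oxct2a, and multicopy genes of the X and Y chromosomes, may share signal, so that the member of a family behind a change is uncertain.

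One linear model with 8 group means was fitted to all arrays (lmFit), contrasts were taken within each experiment, and limma's moderated test was two-sided, with Benjamini-Hochberg adjustment over 12260 genes and an adjusted p threshold of 0.05. The contrasts were tag against wild type and kd-labelled against wild type in each cell type, spermatids against spermatocytes in the wild types of each experiment, the difference of each genotype effect between cell types, the difference between the kd-labelled and the tag effect in each cell type, and the wild types of experiment 2 against those of experiment 1 as a technical check. Values after ± are standard errors of log2 differences unless given as SD, and all fold changes are on the scale of the normalized values. Where a probe was above background on no array of one group, the fold is given as "at least": the mean log2 of the group with signal minus the mean of the other group's arrays, each raised to at least that array's lowest signal above background.

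Gene lists were fixed before the data were examined. They covered the TH2B locus, somatic-type H2B genes, other core and linker histone genes, histone variants, transition proteins and protamines, chromatin remodelling and histone removal, meiotic prophase genes, round spermatid genes, sperm tail and energy genes, and piRNA pathway genes. Markers of Sertoli cells, Leydig cells, peritubular and vascular cells, macrophages and blood, and spermatogonia were also listed. The remaining lists held p53 and apoptosis genes, immediate early and heat shock genes, genes of the double-strand break and DNA damage response, genes on the X chromosome and ribosomal protein genes. Each of the 19 lists with at least 3 measured genes was tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 19 lists. No list passed in any comparison when the correlation was estimated from the residuals instead. Among 190 results for lists, the median, the mean and the direction of the test had the same sign in all 54 that passed, and differed in sign in 29 of the 136 that did not.

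Genes were named by a rule set in advance: the 10 largest changes in each direction past the threshold, the TH2B gene and its neighbour H2ac1, and up to 4 members of each list with the smallest p; for differences between effects, the 5 largest in each direction. Genes named outside this rule are marked as chosen after their values were seen. A spermatid marker score was the mean log2 value of 564 genes more than 2 log2 units higher in spermatids than in spermatocytes among the wild types of experiment 2 and within 0.5 log2 units between tag and wild type in spermatids. A peritubular and vascular marker score was the mean over the 27 measured genes of that list.

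Replicate numbers were checked for pairing by correlating, across genes, the deviations of same-numbered arrays from their group means, with at least 0.1 for every pair as the criterion. By this check numbers paired the tag and wild-type spermatocytes of experiment 1 (correlations from 0.23 to 0.86) and the tag and wild-type spermatids (0.16 to 0.42). They also paired the wild-type spermatocytes and spermatids of experiment 1 (0.13 to 0.57) and of experiment 2 (0.19 to 0.35). They did not pair the kd-labelled and wild-type arrays. The labels do not say what the numbers stand for, so the unpaired model was the primary one and a replicate block an alternative.

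The pipeline was tested on simulated data, drawn independently for each gene from its mean and a spread common to all groups. Known changes were added to genes above the median signal only. The pipeline recovered between 81.0% and 93.0% of genes given a log2 change of 1 and between 31.0% and 43.0% of genes given 0.5, with false calls making up 2.33% to 7.48% of calls, and camera called 0 of 19 random lists. Dim genes, unequal spreads and genes that vary together were therefore not tested. In the data, estimated correlations within lists reached 0.77, and random splits of tagged and wild-type spermatocytes passed a median of 5 lists. The alternatives were normexp with an offset of 50, no background correction, median centring, cyclic loess, the authors' processed values, no filter on dim probes, a stricter filter (detection p under 0.01 in at least 20 arrays), each probe tested separately, the mean of a gene's probes, each experiment alone, the groups of the comparison alone, a replicate block, array weights, a variance trend with robust estimation, a fold threshold of 1.5, an estimated correlation in camera, and leaving out each array. Leaving out 4 spermatocyte arrays (wild-type replicate 1 and tag replicates 1 and 2 of experiment 1, and kd-labelled replicate 1 of experiment 2), and the spermatid marker score as a covariate, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probes without a gene name were left out of the gene counts, and protein measurements were not used here.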

Results

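RNA levels were measured on 44 arrays of male germ cells from adult mice in 8 groups. Experiment 1 held 6 arrays each of wild-type spermatocytes, wild-type round spermatids and both cell types from mice carrying a tagged TH2B allele (TH2B fused at its C terminus to His, Flag and HA). Experiment 2 held 5 arrays each of wild-type and kd-labelled spermatocytes and round spermatids, where kd stands for mice said to make no TH2B protein. TH2B is the testis form of histone H2B, which replaces somatic H2B in meiotic and postmeiotic germ cells. Between 15997 and 19348 of 45281 probes per array were above background, and the number of arrays limits the precision. The first principal component of the 12260 genes held 65.6% of the variance and separated the cell types, with spermatid arrays between -75.2 and -38.9 and spermatocyte arrays between -5.19 and 80.1. Nearest to the spermatids among the spermatocyte arrays lay wild-type replicate 1 and tag replicates 1 and 2 of experiment 1. Among the spermatocyte arrays of experiment 2 the nearest was kd-labelled replicate 1.

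The gene for TH2B, H2bc1 (probe ILMN_2589152, chromosome 13), was read in every group as a check of the labels. Its probe was not above background on any of the 22 wild-type arrays, in spermatocytes or in spermatids. In kd-labelled spermatocytes it was above background on 5 of 5 arrays, at 6.61 ± 0.50 on the log2 scale (SD, n = 5) against 4.61 ± 0.13 in wild-type spermatocytes (SD, n = 5). The signal of this probe was thus at least 3.27-fold higher in kd-labelled spermatocytes (fitted log2 difference 2.01 ± 0.14, adjusted p = 9.97e-14, limma), a direction opposite to the name of the group. In kd-labelled spermatids the fitted log2 difference was 0.37 ± 0.14 (adjusted p = 0.264). There 1 of 5 kd-labelled and 0 of 5 wild-type arrays were above background, so that value is no exact size. The tag groups differed from wild type by -0.01 in spermatocytes (adjusted p = 0.989) and by 0.10 in spermatids (adjusted p = 0.685). Wild-type spermatids and spermatocytes differed by -0.11 in experiment 1 (adjusted p = 0.488) and by -0.05 in experiment 2 (adjusted p = 0.812). Among the tagged and wild-type arrays only 1, of tagged spermatids, was above background. Comparisons between these groups therefore say nothing about the level of TH2B RNA. The kd-labelled difference in spermatocytes passed under each alternative that tested this gene, with fitted sizes between 0.80 without background correction and 2.27 with median centring, and the stricter filter on dim probes left the gene out. Where this probe lies relative to the modified part of the gene is not given in the sources used here, so it may check neither the tag nor the loss of the protein. With no wild-type array above background, the probe may not read the normal RNA, so a rise of that RNA cannot be concluded from it. The neighbouring gene H2ac1, for the testis histone H2A, passed in none of these comparisons, with -0.10 ± 0.19 in kd-labelled spermatocytes (adjusted p = 0.904) and -0.34 ± 0.19 in kd-labelled spermatids (adjusted p = 0.586).

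**Figure D1:**
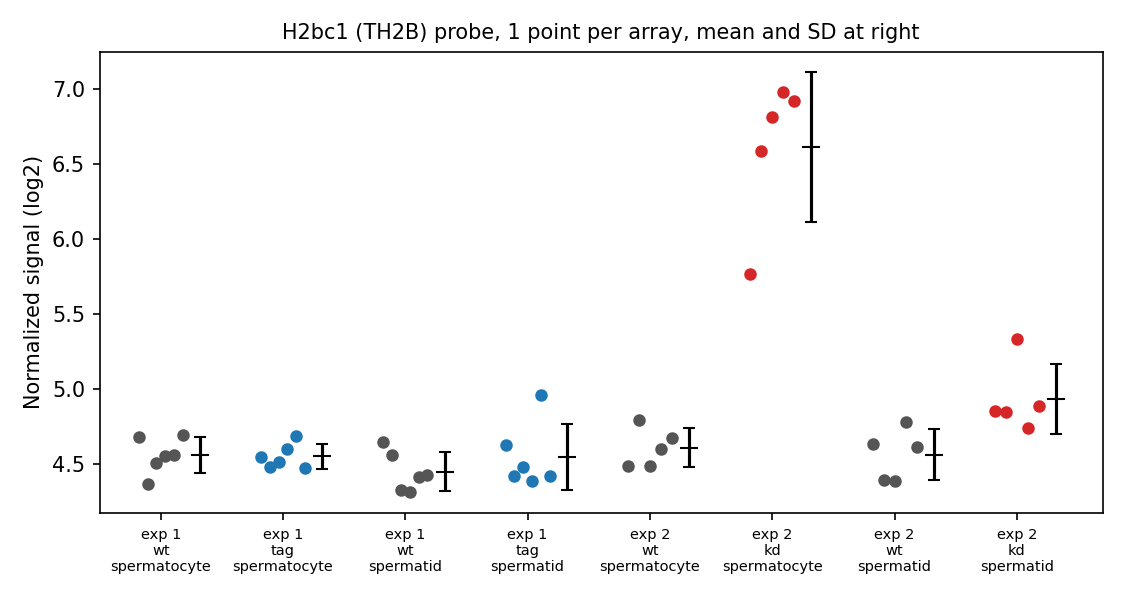
Normalized log2 signal of the H2bc1 probe (vertical axis) on each array, 1 point per array, by group, with the mean and SD at the right of each group. The 5 kd-labelled spermatocyte arrays start at 5.77, above the highest wild-type spermatocyte array of the same experiment at 4.79.

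Tagged against wild-type spermatocytes asked whether the tag on TH2B changes gene expression in meiotic cells. The gene that rose most was 4933436I01Rik, an X-linked gene (4.41 ± 0.22, adjusted p = 2.96e-19). D730045A05Rik, above background on no wild-type spermatocyte array, was at least 4.69-fold higher (adjusted p = 2.62e-11). Some replication-type histone genes rose, among them H4c6 (2.50 ± 0.26, adjusted p = 1.40e-09), H4c9 (2.09) and H4c1 (1.88). The X-linked multicopy genes Ott (2.57) and Cypt2 (2.55), the chitinase-like genes Chil3 (2.55) and Chil4 (at least 4.42-fold), the keratinocyte envelope gene Lor (2.47) and the importin family gene Ranbp6 (2.41) also rose. Nudt16l2 (-3.14 ± 0.32, adjusted p = 1.13e-09), 4931408C20Rik (-2.66), 1110032A03Rik (-2.60), the carbonic anhydrase gene Car2 (-2.47) and the ketone body enzyme gene Oxct2a (-2.47) fell. The actin-capping gene Tmod4 was at least 3.61-fold lower (adjusted p = 3.50e-09).

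Of 10 somatic-type H2B genes 6 rose and none fell, 6 also when adjusted over the list alone, with H2bc21 at 1.34 ± 0.24 and H2bc14 at 0.93 ± 0.19 (list adjusted p = 1.36e-06 with the preset correlation, adjusted p = 0.164 with an estimated correlation). Of 36 other core and linker histone genes 12 rose and 24 did not pass, and adjusted over the list alone 13 rose and 1 fell (list adjusted p = 3.69e-12, adjusted p = 0.164 with an estimated correlation). Among the 389 genes on the X chromosome 60 rose and 1 fell, and adjusted over the list alone 67 rose and 1 fell (list adjusted p = 1.22e-07, adjusted p = 0.792 with an estimated correlation). The spermatid marker score was 8.55 ± 0.70 in tagged and 8.24 ± 0.72 in wild-type spermatocytes (SD, n = 6 each), so the groups differed by less than the spread between arrays. That spread ignores the pairing of same-numbered arrays. Within pairs the tagged array scored higher for replicates 2, 3, 4 and 5 and lower for replicates 1 and 6, a difference that was not tested. The other 16 lists did not pass, with adjusted p from 0.174 to 0.998. Of 73 round spermatid genes 4 rose, among them the X-linked Actrt1, and 2 fell, among them the spermatid kinase gene Tssk6 (-1.38). Of 59 meiotic prophase genes 1 rose (Meioc, 0.46), and none of the 6 transition protein and protamine genes or 15 histone variants passed over all genes. In all 661 genes passed the threshold (511 higher, 150 lower), 225 of them at least 2-fold. Without wild-type replicate 1 the count was 1114, with the groups of the comparison alone 171, with experiment 1 alone 406, with a replicate block 949, and with the spermatid marker score as a covariate 997 (586 higher, 411 lower). The fit shared 1 spread per gene over all 8 groups, though the SD of the spermatid marker score was 0.04 to 0.40 in the other groups. For genes that follow the score, the shared spread may be too small here and the 661 calls too many.

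Tagged against wild-type round spermatids asked the same of postmeiotic cells. Chil4 (4.35 ± 0.20, adjusted p = 1.17e-20) and Chil3 (4.31 ± 0.19, adjusted p = 3.77e-21) rose most among genes with signal in both groups, followed by Ranbp6 (3.99), 4933436I01Rik (3.93), Lor (3.72) and 1700031F05Rik (3.33). D730045A05Rik was at least 12.6-fold higher, the kinase-domain gene Ankk1 at least 8.95-fold, Arhgef26 at least 7.54-fold and the gastric mucosal gene Gkn2 at least 6.78-fold, each above background on 6 of 6 tagged and 0 of 6 wild-type arrays. Tmod4 fell most (-4.12 ± 0.23, adjusted p = 3.49e-18), and 4931408C20Rik (-3.72), Fez1 (-3.58), Gramd2 (-3.23), the necroptosis effector gene Mlkl (-3.14), the potassium channel partner gene Kcnip2 (-3.07) and the vesicle coat gene Sec23a (-2.96) fell too. The spermatogonial transcription factor gene Zbtb16 rose (2.09 ± 0.14, adjusted p = 4.97e-16), as did the glucocorticoid-activating enzyme gene Hsd11b1 (1.28 ± 0.12, adjusted p = 6.07e-12).

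Of 36 other core and linker histone genes 16 rose and 1 fell, with the same counts adjusted over the list alone (H4c3 2.14, H4c9 1.98, H4c6 2.01; list adjusted p = 2.73e-09, adjusted p = 0.549 with an estimated correlation). Of 10 somatic-type H2B genes 3 rose, H2bc21 (1.19), H2bc15 (1.12) and H2bc9 (0.88), and 6 rose adjusted over the list alone (list adjusted p = 0.0111, adjusted p = 0.991 with an estimated correlation). The other 17 lists did not pass (adjusted p from 0.268 to 0.983). Of 389 X-linked genes 57 rose and 10 fell (57 and 11 adjusted over the list alone), with a list adjusted p of 0.381, and the median (-0.00) and mean (0.13) change differed in sign. Of 58 genes for chromatin remodelling and histone removal 5 rose, among them Camk4, a kinase gene needed in spermatids (1.36), and 3 fell, among them Tssk6 (-1.43) and the ubiquitin ligase gene Rnf168 (-0.58). The histone demethylase gene Kdm5b was at 0.47 ± 0.10 (adjusted p = 4.87e-04), a change that turned to -0.14 with the mean of its probes. Meioc rose (1.10), Brca2 fell (-0.46), and of 73 round spermatid genes 2 rose and 6 fell, among them the scaffold gene Pick1 (-0.71) and Cabs1 (-1.02). None of the 6 transition protein and protamine genes passed (H1f7 -0.74, adjusted p = 0.0826). Markers of other cells moved in both directions, with the proteoglycan gene Lum (1.08) and the endothelial gene Egfl7 (1.72) higher and Apoe (-1.11) and Alas2 (-0.57) lower. In all 1984 genes passed (1161 higher, 823 lower), 502 of them at least 2-fold, and with a replicate block 2795 passed.

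The difference of the tag effect between cell types was tested directly. Among the genes whose change was more positive in spermatids was the integrin gene Itgb4 (1.80), and more negative in spermatids were Mlkl (-2.15 ± 0.32, adjusted p = 2.09e-05), Kcnip2 (-2.08) and Gramd2 (-1.93). Arhgef26 (adjusted p = 1.41e-06), the calcium pump regulator gene Sln, the death receptor gene Tnfrsf21 and Chil4 also passed as more positive and Camsap3 and Tmod4 as more negative, each with at least 1 of the 4 groups without an array above background, so that the size of the difference is not known. X-linked genes were less positive in spermatids as a list (4 higher and 1 lower of 389, 3 and 1 adjusted over the list alone; list adjusted p = 0.0382), and ribosomal protein genes more positive (1 higher of 56, also adjusted over the list alone; list adjusted p = 0.0286). Both had an adjusted p = 0.940 with an estimated correlation, and with the authors' processed values the X-linked list had an adjusted p of 0.142. With 1 array left out at a time the X-linked list passed in 12 of 24 cases (0.701 without tagged spermatocyte replicate 1) and the ribosomal list in 17 (0.185 without wild-type spermatocyte replicate 6). The remaining 17 lists did not pass (adjusted p from 0.127 to 0.951). In all 306 genes passed (238 higher, 68 lower), against 100 with the stricter filter on dim probes, 143 with median centring, 171 with cyclic loess or the groups of the comparison alone, 177 with experiment 1 alone and 515 with array weights. Across genes, which are not independent replicates, the tag effects in the 2 cell types had a Pearson r of 0.77 and a Spearman correlation of 0.59. Of the genes called, 410 rose in both cell types where 48.4 would by chance, and 126 fell in both where 10.1 would (Fisher's exact p = 1.16e-125 for the latter). That p value treats genes as independent, and same-numbered wild-type arrays of the 2 cell types were paired, so it overstates the evidence. For the 564 spermatid markers the median ratio of the signal in spermatocytes to that in spermatids was 0.374 with the tag and 0.301 in wild type. Tag effects carried by spermatid RNA in the spermatocyte arrays may therefore add to the overlap, and they were not separated.

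**Figure D2:**
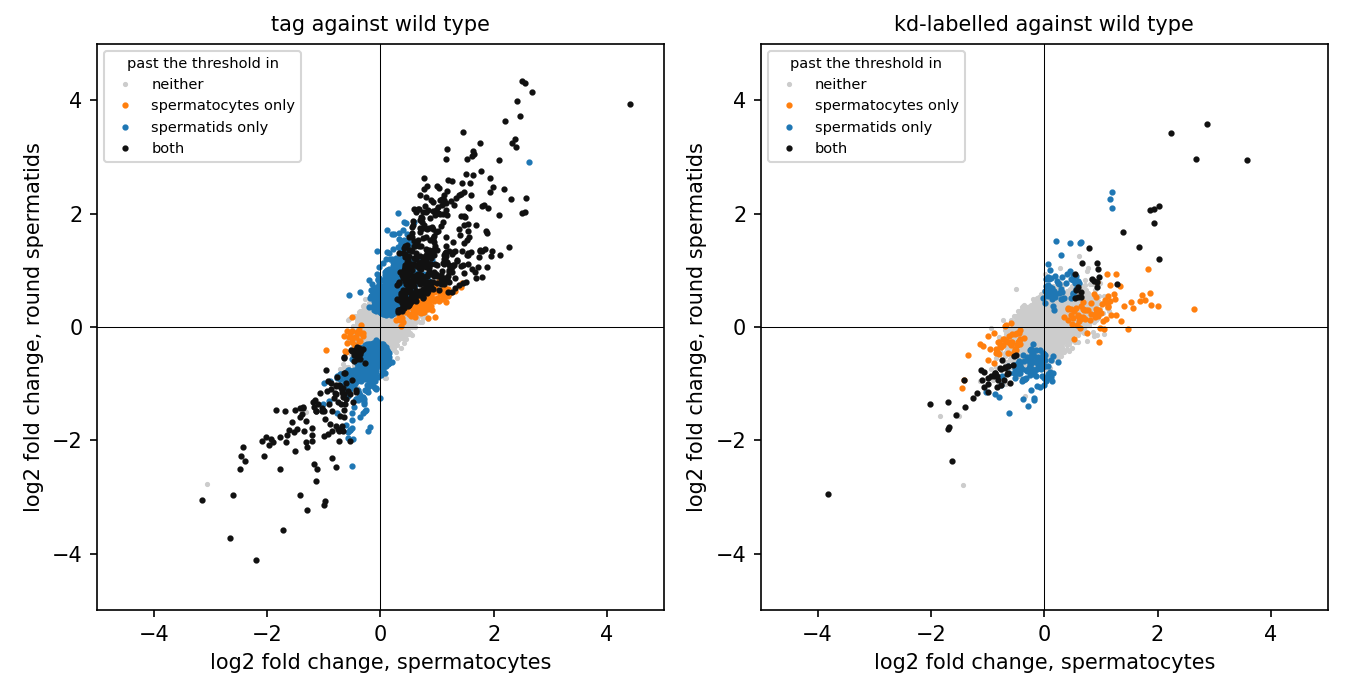
Log2 fold change of each of 12260 genes in spermatocytes (horizontal axis) and round spermatids (vertical axis), for tag against wild type (left) and kd-labelled against wild type (right), coloured by where the gene passed the threshold. Black points passed in both cell types and lie along the diagonal, 410 higher and 126 lower for the tag and 28 higher and 40 lower for kd.

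Kd-labelled against wild-type spermatocytes asked which genes change in meiotic cells said to lack TH2B, with the caveat that its own RNA probe went up. The proteasome subunit gene Psmd8 rose most (3.58 ± 0.22, adjusted p = 2.32e-15), followed by Oit1 (2.86 ± 0.46), the mitotic spindle gene Haus1 (2.68 ± 0.46) and Pnmal1 (2.64). Next were the kinase gene Map4k1 (2.23 ± 0.15, adjusted p = 1.93e-14), the cytochrome gene Cyb5a (2.03), the tubulin gene Tubb6 (2.03) and the forkhead gene Foxa3 (1.93), leaving aside H2bc1, for which only a bound is known. Vav2 fell most (-3.81 ± 0.42, adjusted p = 5.27e-08), followed by the lipid scramblase gene Xkr8 (-2.01), Zfp367 (-1.71), Tedc1 (-1.70) and the importin gene Ipo9 (-1.69). For Vav2, kd-labelled replicate 5 read 9.91, far above the other kd-labelled spermatocyte arrays, so the mean fall does not describe every array. The small heat shock gene Hspb7 was at least 2.30-fold lower (adjusted p = 0.0197).

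Of 10 somatic-type H2B genes 5 rose and none fell, also adjusted over the list alone, with H2bc11 at 1.73 ± 0.23, H2bc14 at 1.69 ± 0.21, H2bc7 at 1.17 ± 0.24 and H2bc6 at 1.13 ± 0.24 (list adjusted p = 4.02e-10, adjusted p = 0.0580 with an estimated correlation). Other core and linker histone genes did not pass as a list (0 higher and 1 lower of 36, 1 and 2 adjusted over the list alone; adjusted p = 0.177), and H4c2 fell (-0.77). Markers of smooth muscle and vessels rose in 7 of 27 cases, 10 adjusted over the list alone, with the contractile genes Myl9 (1.88 ± 0.34), Tpm1 (1.41 ± 0.30) and Tpm2 (1.18 ± 0.21) and the matrix gene Bgn (1.57 ± 0.29). That list had an adjusted p of 3.31e-10 (adjusted p = 0.143 with an estimated correlation). Its mean level was 6.62 ± 0.37 in kd-labelled and 6.02 ± 0.27 in wild-type spermatocytes (SD, n = 5 each). Among 23 immediate early and heat shock genes 3 rose, Zfp36 (1.12), Egr1 (1.07) and Ier3 (0.59), and 5 rose adjusted over the list alone (list adjusted p = 6.47e-04, adjusted p = 0.115 with an estimated correlation). The Sertoli cell list passed upward with 1 of 18 genes past the threshold, also adjusted over the list alone, the filament gene Vim (0.97; list adjusted p = 0.00211, adjusted p = 0.478 with an estimated correlation).

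The X-linked list also passed upward in kd-labelled spermatocytes, with 3 of 389 genes past the threshold, also adjusted over the list alone, and a median change of 0.18 (list adjusted p = 6.47e-10, adjusted p = 0.372 with an estimated correlation). Besides Bgn these were the transporter gene Slc38a5 (1.87) and Morf4l2 (0.94), named after their values were seen. The ribosomal protein list (56 genes, median 0.09, adjusted p = 4.24e-04), the round spermatid list (73 genes, median 0.19, adjusted p = 0.00248) and the transition protein and protamine list (6 genes, median 0.31, adjusted p = 0.0321) passed upward with 0 members past the threshold in limma's test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 8 ribosomal protein genes were higher and 1 lower, 7 round spermatid genes higher and 2 lower, and 1 protamine gene higher. With an estimated correlation the adjusted p was 0.372 for the first and 0.478 for the others. The spermatid marker score stood beside this at 7.88 ± 0.40 in kd-labelled and 7.57 ± 0.11 in wild-type spermatocytes (SD, n = 5 each). With that score as a covariate the adjusted p was 0.484 for round spermatid genes and for protamines and 0.224 for Sertoli markers, and without kd-labelled replicate 1 the same lists had 0.142, 0.426 and 0.103. The protamine list passed in 5 of 10 cases with 1 array left out. The other 11 lists did not pass (adjusted p from 0.0992 to 0.806). In all 191 genes passed (101 higher, 90 lower), 64 of them at least 2-fold. The count was 120 without kd-labelled replicate 1 and 113 with the groups of the comparison alone, against 353 with experiment 2 alone, 469 with array weights, 310 with cyclic loess and 305 with the spermatid marker score as a covariate. A replicate block gave 524, though kd-labelled and wild-type arrays were not paired by number.

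**Figure D3:**
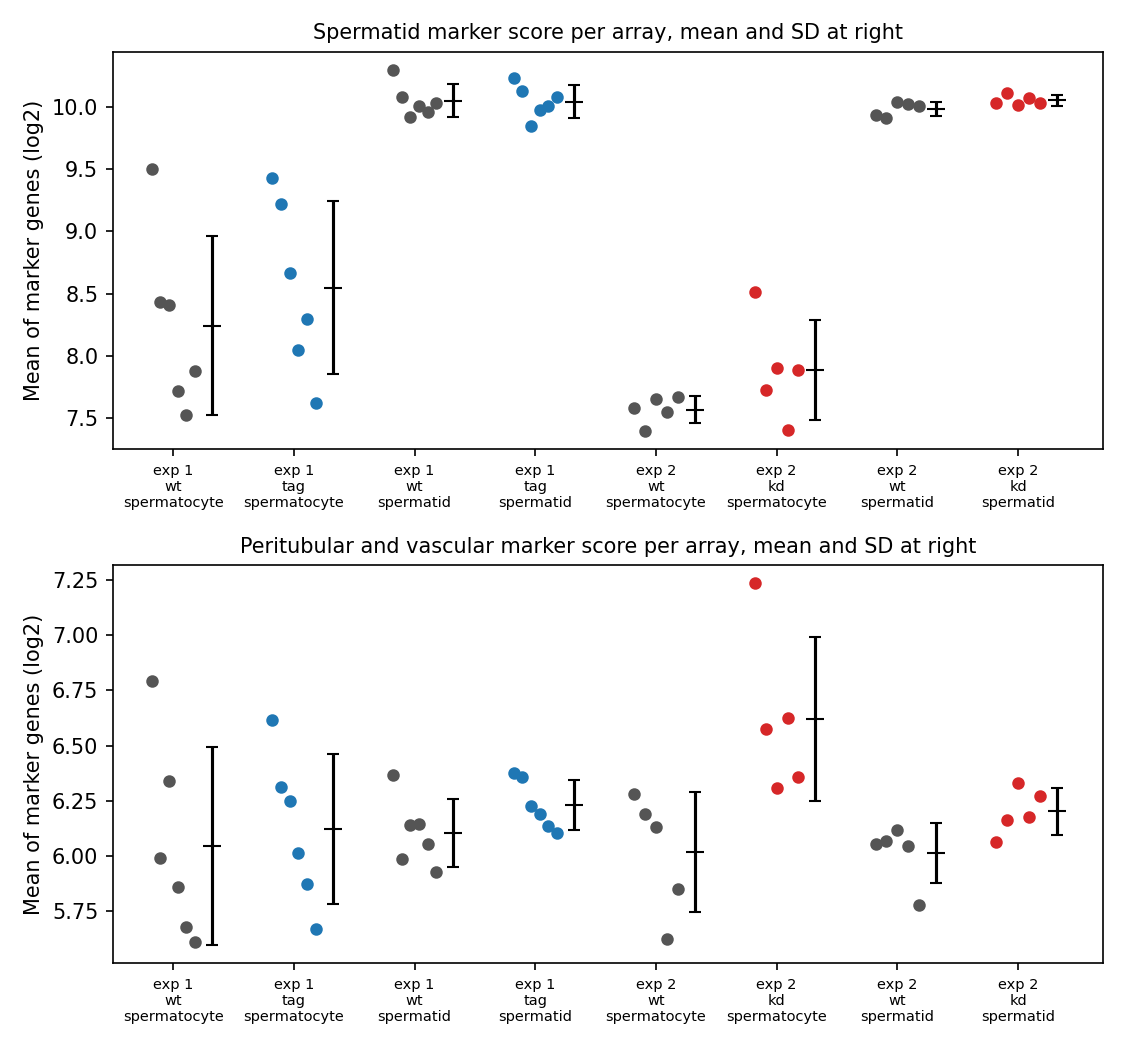
Mean log2 signal of 564 spermatid marker genes (top) and of 27 peritubular and vascular marker genes (bottom) on each array, 1 point per array, with the mean and SD at the right of each group. Spermatocyte arrays of experiment 1 spread from 7.52 to 9.50 on the spermatid score, and kd-labelled spermatocytes lie from 6.31 to 7.23 on the vascular score against 5.62 to 6.28 in the wild type.

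Kd-labelled against wild-type round spermatids asked the same of postmeiotic cells. Oit1 (3.58 ± 0.46, adjusted p = 2.35e-06), Map4k1 (3.43 ± 0.15, adjusted p = 4.35e-21), Haus1 (2.96) and Psmd8 (2.95 ± 0.22, adjusted p = 1.03e-12) rose most. The pregnancy-specific glycoprotein gene Psg19 (2.26), Tubb6 (2.13), the chloride channel gene Cftr (2.09), Foxa3 (2.08) and the scaffold gene Dlg1 (2.06) also rose. Vav2 fell most (-2.94 ± 0.42, adjusted p = 1.79e-05), Hspb7 was at least 3.60-fold lower (adjusted p = 2.06e-04), and Tedc1 (-1.80), Ipo9 (-1.77), the Golgi mannosidase gene Man2a2 (-1.52) and the retinal gene Rd3 (-1.42) fell. Here too kd-labelled replicate 5 stood far above the rest of its group for Vav2 (9.75). Of 10 somatic-type H2B genes 3 rose, 4 adjusted over the list alone, namely H2bc4 (2.38 ± 0.57), H2bc15 (1.49 ± 0.27) and H2bc9 (0.85 ± 0.23) over all genes (list adjusted p = 0.00119, adjusted p = 0.807 with an estimated correlation). None of the 6 transition protein and protamine genes passed, with Tnp1 at 0.09 ± 0.17 (adjusted p = 0.939) and Prm1 at -0.06 ± 0.10 (adjusted p = 0.932). None of 36 other core and linker histone genes and none of 73 round spermatid genes passed, over all genes or adjusted over the list alone (6 histone genes higher and 1 lower, and 5 spermatid genes lower, at an unadjusted p under 0.05). Camk4 rose (0.81), the meiotic kinase gene Aurkc (-0.91) and the piRNA gene Asz1 (-0.58) fell, the cell death gene Bbc3 rose (1.27 ± 0.22, adjusted p = 3.11e-04) and the matrix gene Fn1 rose (0.70).

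The X-linked list (389 genes, median 0.11, adjusted p = 0.00280) and the spermatogonial list (22 genes, median 0.18, adjusted p = 0.00830) passed upward in kd-labelled spermatids with 0 genes past the threshold in limma's test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 13 X-linked genes were higher and 6 lower, and 2 spermatogonial genes were higher. With an estimated correlation the adjusted p was 0.891 and 0.807, and without kd-labelled replicate 5 the spermatogonial list had an adjusted p of 0.0569. The vascular list was at an adjusted p of 0.0514, with mean levels of 6.20 ± 0.10 and 6.01 ± 0.13 in kd-labelled and wild-type spermatids (SD, n = 5 each). The 16 lists that did not pass had an adjusted p from 0.0514 to 0.986. In all 232 genes passed (85 higher, 147 lower), 53 of them at least 2-fold. With median centring 58 were higher and 163 lower, and the count was 350 with experiment 2 alone, 364 with the groups of the comparison alone, 484 with a replicate block and 749 with array weights.

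The kd-labelled effect differed between cell types for 6 genes (1 higher and 5 lower in spermatids, with 508 genes at an unadjusted p under 0.05). Map4k1 was more positive in spermatids (1.19 ± 0.21, adjusted p = 0.00727). H2bc1 (adjusted p = 6.31e-06), Pnmal1, the kallikrein gene Klk1b22, the engulfment gene Elmo3 and the microfibril gene Mfap4 passed as more negative there, each with at least 1 of the 4 groups without an array above background, so that the size of the difference is not known. With median centring 0 were higher and 5 lower. The count was 2 with the stricter filter on dim probes, 10 with cyclic loess, 11 with each probe tested separately, 12 without kd-labelled spermatocyte replicate 1 of experiment 2 and the 3 arrays of experiment 1 nearest to the spermatids, and 28 with array weights. As lists, vascular markers (adjusted p = 7.74e-05), round spermatid genes (0.00421), somatic-type H2B genes (0.00537), sperm tail and energy genes (0.00537), X-linked genes (0.00956) and Sertoli markers (0.0204) were less positive in spermatids. None of these calls held with an estimated correlation, where the lowest adjusted p was 0.572. Over all genes none of their members passed in limma's test (6 vascular, 5 H2B, 5 X-linked, 2 round spermatid, 1 sperm tail and 1 Sertoli gene were lower and 3 X-linked, 1 vascular and 1 H2B gene higher at an unadjusted p under 0.05). Adjusted over the list alone, 3 vascular genes, 1 Sertoli gene and 2 H2B genes were lower and 1 H2B gene was higher. Without kd-labelled spermatocyte replicate 1 the round spermatid (adjusted p = 0.161), X-linked (0.759) and Sertoli (0.352) lists did not pass, and with 1 array left out at a time these passed in 19, 17 and 12 of 20 cases. With the authors' processed values 3 lists passed, with H2B (0.0759), X-linked (0.0759) and Sertoli genes (0.0585) not among them. Across genes the kd-labelled effects in the 2 cell types had a Pearson r of 0.57, with 28 genes higher in both (0.700 by chance, Fisher's exact p = 1.19e-38) and 40 lower in both (1.08 by chance, exact p = 1.69e-54). These p values treat genes as independent replicates. Same-numbered wild-type arrays of the 2 cell types were also paired, so the p values overstate the evidence. Whether spermatid RNA in the spermatocyte arrays adds to this overlap was not tested.

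The kd-labelled and the tag effect were also compared with each other. Of 36 other core and linker histone genes 12 passed as more negative for kd in spermatocytes (also adjusted over the list alone; list adjusted p = 2.76e-06, adjusted p = 0.444 with an estimated correlation). In spermatids 14 did (adjusted over the list alone 15 lower and 1 higher; list adjusted p = 4.03e-05, adjusted p = 0.951 with an estimated correlation). Somatic-type H2B genes did not pass as a list (adjusted p = 0.303 and 0.872). Vascular markers (3 higher of 27; adjusted over the list alone 7 higher and 1 lower; adjusted p = 4.90e-05), immediate early genes (2 higher of 23, also adjusted over the list alone; adjusted p = 0.00190), ribosomal protein genes (adjusted p = 0.00286) and Sertoli markers (adjusted p = 0.0341) were more positive in kd-labelled spermatocytes. The only ribosomal protein gene of 56 past the threshold was lower, also adjusted over the list alone, and none of 18 Sertoli genes passed in limma's test either way. At an unadjusted p under 0.05, 10 ribosomal protein genes were higher and 1 lower, and 2 Sertoli genes were higher. With an estimated correlation the lowest adjusted p over all lists was 0.156. Psmd8 (3.75 ± 0.30, adjusted p = 1.74e-11) and Pnmal1 (2.76) were among the genes more positive for kd in spermatocytes, and 4933436I01Rik (-3.72 ± 0.32, adjusted p = 7.94e-11) and Vav2 (-3.73) among those more negative. In spermatids Fez1 (3.88 ± 0.37) and Tmod4 (3.39 ± 0.34) were more positive and Ranbp6 (-4.55 ± 0.35) and Chil4 (-4.29 ± 0.30) more negative. In all 273 genes (108 higher, 165 lower) differed in spermatocytes and 1197 (488 higher, 709 lower) in spermatids. With a replicate block the counts were 545 and 1792, and with the authors' processed values 214 and 1262. Further settings are given below. The effects had a Pearson r across genes of 0.20 in spermatocytes and 0.08 in spermatids. Of the genes called in spermatids, 27 rose with both alleles (8.05 by chance) and 30 fell with both (9.87 by chance). There 8 rose with the tag and fell for kd, and 6 the reverse way. In spermatocytes 10 rose with both (4.21 by chance) and 9 fell with both (1.10 by chance), with 0 and 1 in opposite directions.

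**Figure D4:**
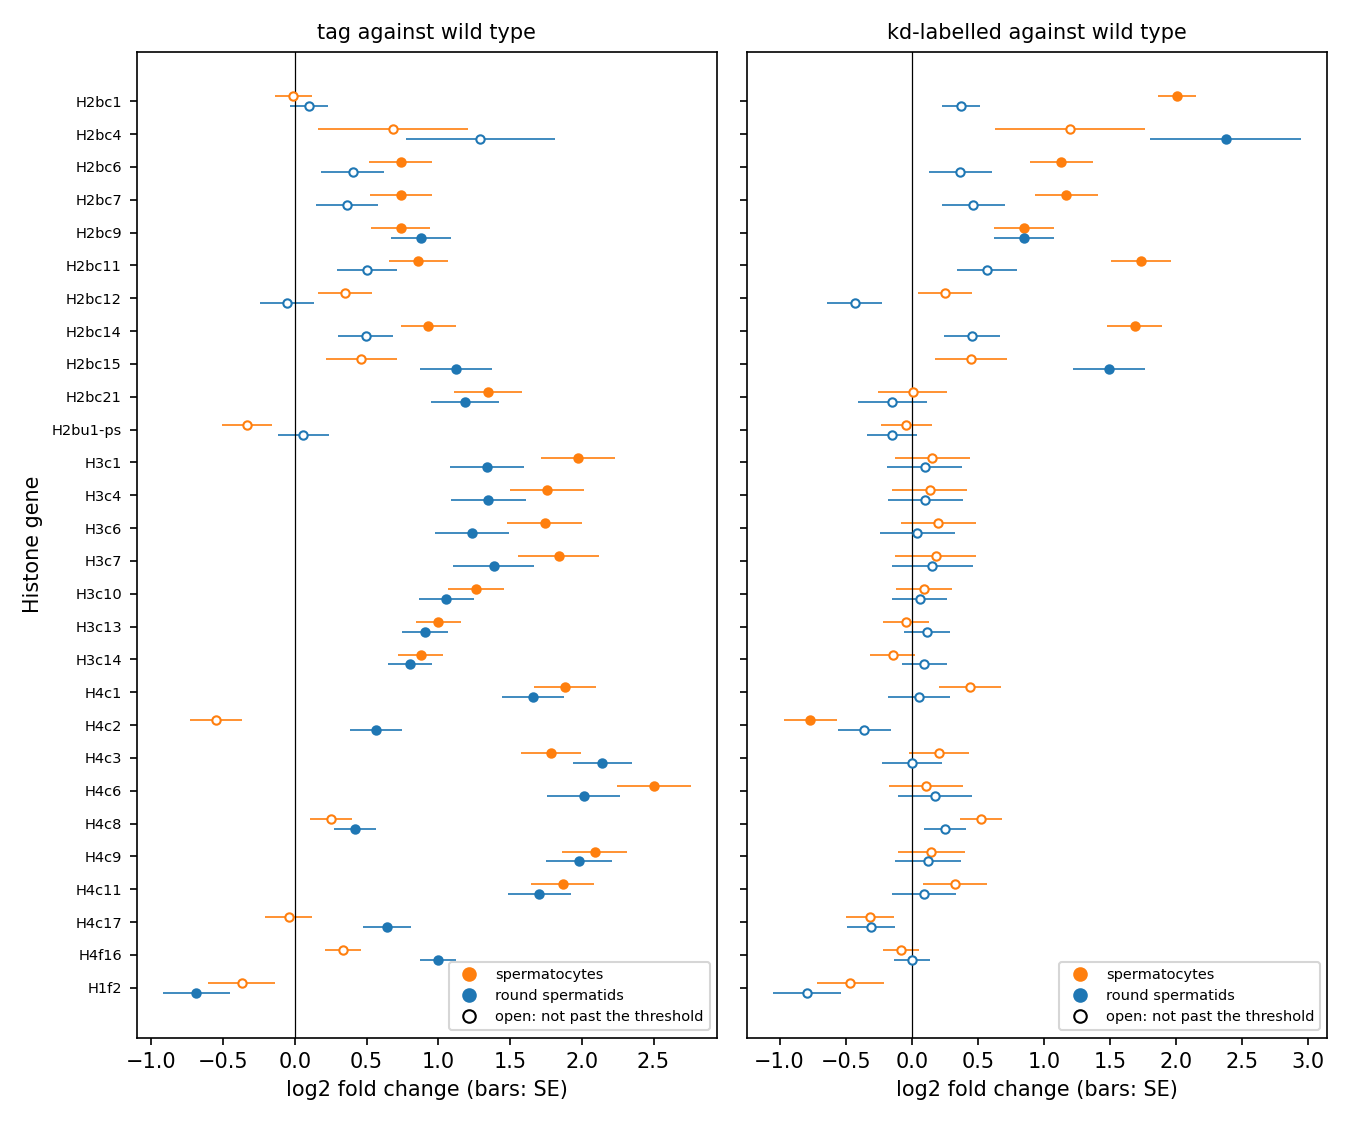
Log2 fold change with its standard error (horizontal axis) of the H2B genes and of each other core or linker histone gene past the threshold in at least 1 of 4 comparisons, for tag (left) and kd-labelled cells (right), with open points for genes not past the threshold. In tagged spermatocytes 12 H3 and H4 genes passed to the right. In kd-labelled spermatocytes 5 somatic-type H2B genes passed to the right, and the only H3 or H4 gene that passed was H4c2, to the left (-0.77).

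Wild-type spermatids were compared with wild-type spermatocytes in each experiment to describe the cell types. Among genes that rose in experiment 2 were the sperm fibrous sheath gene Ropn1 (2.94 ± 0.22), the acrosomal gene Zp3r (2.63 ± 0.23), Spem2 (3.32), Car2 (3.59 ± 0.34, adjusted p = 4.43e-12) and Paqr5 (3.43). The piRNA genes Tdrd5 (-3.97 ± 0.20) and Piwil1 (-2.81 ± 0.14), the septin gene Septin12 (-4.91 ± 0.25, adjusted p = 7.84e-20), the POU factor gene Pou5f2 (-4.69) and the sulfotransferase gene Chst1 (-4.30) fell. In experiment 1 the same genes Septin12 (-4.94 ± 0.23), Pou5f2 (-4.40), Piwil1 (-3.64 ± 0.13) and Tdrd5 (-3.63) fell, and Dcn (2.77 ± 0.28), Actrt1 (2.48), Sppl2c (2.42) and Ropn1 (1.83) rose. Gene lists passed between the cell types at the preset correlation alone, and none at an estimated one (lowest adjusted p 0.340 in experiment 1 and 0.306 in experiment 2). Round spermatid genes rose in 51 and fell in 10 of 73 cases in experiment 1 (adjusted p = 6.56e-07) and in 52 and 9 in experiment 2 (adjusted p = 7.98e-10). Of 6 transition protein and protamine genes 5 rose in each (adjusted p = 0.0172 and 0.00224), with Tnp2 at 1.23 ± 0.18 and 2.47 ± 0.20. X-linked genes rose in 212 and fell in 12 of 389 cases in experiment 1 (adjusted p = 2.13e-11) and in 209 and 11 in experiment 2 (adjusted p = 5.74e-11). Somatic-type H2B genes rose in 7 and fell in 1 of 10 cases (adjusted p = 0.0237) and in 8 and 1 (adjusted p = 0.00305).

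Among lists that fell in spermatids, likewise at the preset correlation alone, were piRNA pathway genes (3 higher and 17 lower of 23 in both experiments, adjusted p = 0.00116 and 0.00224), meiotic prophase genes (12 and 30 of 59, then 8 and 28; adjusted p = 0.0122 and 0.0278) and ribosomal protein genes (2 and 31 of 56, then 2 and 30; adjusted p = 0.00545 and 0.00528). Chromatin remodelling and histone removal genes (11 and 32 of 58, then 13 and 33; adjusted p = 0.0237 and 0.0294) and DNA damage response genes (9 and 26 of 50, then 10 and 27; adjusted p = 0.0237 and 0.0385) fell too. Leydig cell markers were lower in spermatids (2 and 8 of 11, then 0 and 8; adjusted p = 0.0122 and 0.00528), with the hormone gene Insl3 at -3.07 and -3.41. Macrophage and blood markers were higher (15 and 0 of 16, then 9 and 0; adjusted p = 4.81e-05 and 0.00634), with the complement gene C1qb at 2.52 and 2.16. Other core and linker histone genes (13 and 5 of 36, adjusted p = 0.0793; then 20 and 5, adjusted p = 0.00528) and sperm tail and energy genes (25 and 14 of 54, adjusted p = 0.127; then 26 and 18, adjusted p = 0.0385) passed upward in experiment 2. With a replicate block the latter had an adjusted p of 0.0517, and without wild-type spermatocyte replicate 4 the DNA damage response list had an adjusted p of 0.0502. Adjusted over the list alone, no count of the lists that passed moved by more than 1 gene. Histone variants (5 and 6 of 15, then 5 and 7), Sertoli markers (6 and 1 of 18, then 7 and 0), vascular markers (6 and 8 of 27, then 6 and 9), spermatogonial markers (3 and 3 of 22, then 5 and 4), p53 and apoptosis genes (5 and 16 of 34, then 3 and 15) and immediate early genes (5 and 5 of 23, then 5 and 4) did not pass in either. Their counts moved by at most 2 genes adjusted over the list alone.

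In all 7542 genes passed between wild-type cell types in experiment 1 (3413 higher, 4129 lower) and 7600 in experiment 2 (3300 higher, 4300 lower), with a Pearson r across genes of 0.95 between the experiments. Median centring moved the median of all genes to -0.15 and -0.14, and in experiment 1 the split became 2618 higher and 4845 lower. As a technical check, the wild types of experiment 2 differed from those of experiment 1 for 3159 genes in spermatocytes and 3409 in spermatids. Experiment and batch cannot be separated in these contrasts.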

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

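The tests of signal from other H2B transcripts and of replicate deviations, the use of the spermatid marker score, and the comparison of called histone and X-linked genes with and without it, were chosen only after the results were seen.

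The H2bc1 probe was at least 3.27-fold higher in kd-labelled than in wild-type spermatocytes, where it was on no array above background, against the meaning of the group's name. Signal from the 10 other measured H2B genes on the probe is argued against. Of these, 8 were at least as high in wild-type spermatids as in kd-labelled spermatocytes. In wild-type spermatids the highest H2bc1 value was 4.78, below the lowest of 5.77 in kd-labelled spermatocytes. The others were at least as high in groups with little or no signal of the probe. H2bu1-ps was so in wild-type spermatocytes (6.02, against 5.97 in kd-labelled ones, with H2bc1 at 4.61). H2bc4 was so in kd-labelled spermatids (9.27, against 7.49 in kd-labelled spermatocytes, with H2bc1 at 4.93). The fixed list held 18 such genes, and those not measured were not tested. Probes of these near-identical genes may share signal, so the level of each is uncertain. RNA that vascular and peritubular cells of all the mice make is argued against. Of 8 arrays of other groups with a vascular score above the lowest kd-labelled spermatocyte array, 7 did not have the probe above background. These 7 were all wild-type or tagged, so they cannot decide on RNA that such cells make in kd-labelled mice alone, which stays open. The only kd-labelled array among the 8, spermatid replicate 3 at a score of 6.33, had the probe above background. Without kd-labelled spermatocyte replicate 1, the array with the highest vascular score, the fitted difference was 2.22 ± 0.12 (adjusted p = 1.22e-17, limma). A transcript of the modified allele that this probe reads stays open and untested, since the position of the probe relative to the modification is not given in the sources used here. The probe was above background on no wild-type array, though TH2B replaces somatic H2B in these cells. It may therefore not read the normal RNA, and a rise of that RNA cannot be concluded from it.

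In tagged spermatocytes 661 genes passed while the spermatocyte arrays of experiment 1 varied in spermatid marker score. Uneven spermatid content as the whole cause of the calls is argued against: 96.2% of them (636 of 661) remained with the score as a covariate, among them 12 of 12 other core and linker histone genes (median 1.55, against 1.81 without the score) and 60 of 60 X-linked genes (median 0.86, against 1.17). For these lists as a whole it stays open: with the score the medians went from 0.20 to 0.06 and from 0.07 to 0.01, so that an adjusted p of 1.50e-11 and 0.00446 at the preset correlation, 0.0929 and 0.708 at an estimated one, excludes nothing there. The score measures only the amount of spermatid RNA, through genes chosen as unchanged by the tag in spermatids. It cannot remove tag effects carried by spermatid RNA present in both groups, so that source of the calls stays open too. For 52 genes above background in tagged spermatids and in no wild-type array of experiment 1, the median ratio of the signal in tagged spermatocytes to that in tagged spermatids was 0.362, against 0.374 for 564 spermatid markers (95% interval of the difference -0.0602 to 0.0155), but only 9 of them were above background on every tagged spermatocyte array, so the ratio rests largely on signal near background and leaves open whether spermatid RNA is the source of their signal there. An effect of the tagged allele, and of other differences between the mice, stays open and untested.

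Among 354 genes called in kd-labelled cells, 19 had the next tested gene on the chromosome called too, against a mean of 9.58 and a highest value of 20 in 1000 shuffles (10 pairs shared a direction), among them the runs Map4k1, Ryr1 and Rasgrp4 on chromosome 7 and Asz1, Cftr, Lsm8 and Ankrd7 on chromosome 6 of GRCm38.p6, singled out after their values were seen. The deviations of same-numbered arrays of the 2 cell types had a mean correlation across these genes of 0.465, against 0.406 at most in 200 random sets. Single wild-type replicates stood near the kd-labelled mean in both cell types, as replicate 5 for Oit1 (7.18 and 8.32) and replicate 4 for Haus1 (8.84 and 8.65). These values are what linked genetic variants that differ between the mice would give, which may account for some of the calls, and they do not separate such variants from the modified allele. In tagged spermatids 297 of 1981 called genes had a called neighbour (172 pairs shared a direction), against a mean of 300.3 and a highest value of 347 in shuffles. The calls there were thus not clustered beyond shuffles, which gives no sign of linked variants as their main source. With so many calls the test cannot see linked variants behind a small share of them, or variants spread over the genome.

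Single replicates far from the rest of their group were sought with Dixon's test, which chance passes in about 1 in 20 groups. Array measures had 4 of 40 such cases, and named genes 73 of 657 (11.1%). Among the latter was Vav2, with kd-labelled replicate 5 far above its group in spermatocytes (9.91) and in spermatids (9.75). The H2bc1 probe read 5.34 on kd-labelled spermatid replicate 3, with the next array at 4.89. Wild-type spermatid replicate 1 of experiment 1 had 16150 probes above background, with the next at 16817. Kd-labelled spermatid replicate 4 had 16729, with the next at 17165. The vascular marker score of wild-type spermatid replicate 5 of experiment 2 was 5.78, with the next at 6.05.

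Effects that differed between the cell types were tested as an interaction. The tag effect differed for 306 genes and 2 lists, and the kd-labelled effect for 6 genes and 6 lists. The fitted kd-labelled differences, spermatids minus spermatocytes, were -1.64 for H2bc1, 1.19 for Map4k1, -2.31 for Pnmal1, -1.09 for Elmo3, -1.52 for Klk1b22 and -1.08 for Mfap4, and all but that of Map4k1 rest on at least 1 group without an array above background, so that they are no exact sizes. Of 10396 probes left out for lack of a single gene name, 37 were above background on every tagged and no wild-type spermatid array of experiment 1 (8 the reverse way, and 108 against 24 among named probes). The same held for 3 in tagged spermatocytes (2 the reverse way; named probes 20 against 5), for 6 in kd-labelled spermatocytes (0 the reverse way; 23 against 2) and for 1 in kd-labelled spermatids (2 the reverse way; 9 against 7).

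Random splits of the same arrays into groups of the same sizes as the real ones, 100 drawn for each comparison with the real one included, were counted by how many gave a result as large. Chance was excluded for the 1984 genes of tagged spermatids (1 split, highest other 851), the 191 of kd-labelled spermatocytes (1, highest other 48), the 232 of kd-labelled spermatids (1, highest other 174) and the wild-type cell types of experiment 1 (1; 7542 with 5099). By the share of splits it was also excluded for the wild types between experiments (1 each; 3159 with 3138 and 3409 with 2413). In spermatocytes the margin was small, since a random split gave 3138 genes against 3159. It was not excluded for tagged spermatocytes, where 8 splits reached 661 and the highest gave 4408, nor for the tag interaction, where 8 reached 306 and the highest gave 1877. For the kd-labelled minus tag effect 3 splits reached 273 genes in spermatocytes (highest other 2220) and 1 reached 1197 in spermatids (highest other 57), without regard to the pairs of experiment 1. Counts several times the real one, as in these spermatocytes too, show that the arrays also differ along lines other than genotype. What those lines are was not tested. The 6 genes of the kd-labelled interaction were reached by 5 splits (highest other 18), so chance was not excluded.

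Same-numbered arrays were paired between tag and wild type within each cell type of experiment 1 and between the wild-type cell types of each experiment, and not between the other groups, and splits that part every pair balance the pairs between the groups. Of 32 such splits only the real one reached 661 genes in tagged spermatocytes (highest other 315), 1984 in tagged spermatids (750) and 7542 between the wild-type cell types (6247), and chance was excluded in each. For tagged spermatocytes this rests on the pairing, since 8 of 100 splits without regard to it reached 661. The pairing was inferred from these same data, and own numbers correlated best for only 3 of 6 arrays between wild-type and tagged spermatocytes. Chance was also excluded for the kd-labelled minus tag effect, where the pairs of experiment 1 were parted and the unpaired arrays of experiment 2 split freely: 3 of 100 reached 273 genes in spermatocytes (highest other 307) and 1 of 100 reached 1197 in spermatids (highest other 878). Between the wild-type cell types of experiment 2, 1 of 100 random splits reached 7600 genes (highest other 5391), but these arrays are paired and only 16 splits part every pair. Those are too few for a share under 0.05, with 7600 genes in the real one and 5315 in the highest other. For the tag interaction 7 of 100 reached 306 (highest other 1362), so chance was not excluded.

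For gene lists, 4 of 100 splits reached the 13 lists of the wild-type cell types of experiment 2 (highest other 13), but these splits pass over the pairing of the arrays. The 16 that part every pair are too few for a share under 0.05 (3 reached 13 lists, highest other 13). Chance was not excluded elsewhere. As many lists passed in 78 splits for tagged spermatocytes (3 lists, highest other 13), 62 for tagged spermatids (2, highest 6), 35 for kd-labelled spermatocytes (8, highest 17) and 37 for kd-labelled spermatids (3, highest 6). The same was true of 15 splits for the wild-type cell types of experiment 1 (11, highest 14), 82 for the tag interaction (2, highest 14) and 39 for the kd-labelled interaction (6, highest 14). Nor was it excluded by splits that part every pair, where as many lists passed in 18 of 32 for tagged spermatocytes (highest other 8), 14 of 32 for tagged spermatids (4), 7 of 32 for the wild-type cell types of experiment 1 (14) and 58 of 100 for the tag interaction (9).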

How the results depend on the processing

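The tests without 4 spermatocyte arrays (wild-type replicate 1 and tag replicates 1 and 2 of experiment 1, kd-labelled replicate 1 of experiment 2), and those with the spermatid marker score, were chosen after seeing the data. Of 375 named changes past the threshold, 375 kept direction and call with a replicate block, 374 with array weights and 356 with the authors' processed values. With median centring 349 did, and with the groups of the comparison alone 332. Named genes were chosen for large changes or small p, so they need not stand for all calls. Over all calls the authors' processed values kept 79.1% in tagged spermatocytes. Across comparisons they kept from 66.7% (kd-labelled interaction, 4 of 6) to 97.9% (wild-type cell types of experiment 1). Leaving out the 4 spermatocyte arrays kept 65.1% in tagged and 74.9% in kd-labelled spermatocytes. Kdm5b in tagged spermatids turned, to -0.14 with the mean of its probes, and the cause was not tested. The fitted H2bc1 change in kd-labelled spermatocytes passed in each alternative that tested it, from 0.80 to 2.27; the stricter filter on dim probes left it out. With probes in place of genes, more features being tested, the counts were 1077 in tagged spermatocytes (661 genes), 3498 in tagged spermatids (1984), 340 in kd-labelled spermatocytes (191), and 13256 and 13432 between the wild-type cell types (7542 and 7600). They were 560 and 11 for the tag (306) and kd-labelled (6) interactions, and 497 and 2091 for the kd-labelled minus tag effect in spermatocytes (273) and spermatids (1197). A fold of at least 1.5, by construction a smaller set, left 1136 in tagged spermatids. The cause was not tested for the following values. Each experiment alone gave 406 in tagged spermatocytes, 353 and 350 in kd-labelled spermatocytes and spermatids (232 in the latter), and 177 for the tag interaction. The groups of the comparison alone, with fewer arrays behind the spread, gave 171 in tagged spermatocytes, 113 and 364 in kd-labelled spermatocytes and spermatids, 171 for the tag interaction and 117 for the kd-labelled minus tag effect in spermatocytes. This setting also drops the spread shared by all 8 groups, whose spermatid marker scores had an SD from 0.04 to 0.72. A shared spread may be too small for the spermatocytes of experiment 1 and too large for the spermatids of experiment 2. Array weights gave 469 and 749 in kd-labelled spermatocytes and spermatids, 515 and 28 for the tag and kd-labelled interactions and 478 and 2054 for the kd-labelled minus tag effects. Cyclic loess gave 310 in kd-labelled spermatocytes and 171 and 10 for the interactions, median centring 143 for the tag interaction, and the stricter filter on dim probes, with fewer genes tested, 100 and 2 for the interactions. The spermatid marker score gave 997 in tagged and 305 in kd-labelled spermatocytes, with 5 lists in the latter (8 without it). Leaving out the 4 spermatocyte arrays gave 12 for the kd-labelled interaction, 482 in tagged and 165 in kd-labelled spermatocytes. Kd-labelled and wild-type arrays were not paired by number: own numbers correlated from -0.06 to 0.40 in spermatocytes, best for 3 of 5 arrays, and from -0.05 to 0.14 in spermatids, best for 1 of 5. A replicate block gave 524 genes in spermatocytes, 484 in spermatids, 14 for the interaction and 545 for the kd-labelled minus tag effect in spermatocytes. In the tag comparisons, where numbers did pair, the block gave 949 genes in spermatocytes (661) and 2795 in spermatids (1984). The block changed no other named call except that of the sperm tail and energy list between the wild-type cell types of experiment 2 (adjusted p = 0.0517). An estimated correlation left 0 lists in each of 10 comparisons. The authors' processed values left 1 list for the tag interaction (2) and 3 for the kd-labelled one (6). Leaving out 1 array at a time, the lowest and highest counts were 468 and 1114 in tagged spermatocytes (1114 without wild-type replicate 1) and 120 and 273 in kd-labelled spermatocytes (120 without kd-labelled replicate 1). For lists they were 5 and 12 in kd-labelled spermatocytes (5 without kd-labelled replicate 1) and 2 and 6 in kd-labelled spermatids (3 in all; 5 without wild-type replicate 1 or 2 or kd-labelled replicate 1 or 2, 6 without kd-labelled replicate 4). For the tag interaction they were 0 and 3 lists: 0 without wild-type spermatocyte replicate 4, 5 or 6, tagged spermatocyte replicate 1 or 2 or wild-type spermatid replicate 1, and 1 without tagged spermatocyte replicate 3, wild-type spermatid replicate 2 or 4 or tagged spermatid replicate 1, 3, 5 or 6. For the kd-labelled interaction they were 3 and 9 lists, 3 without kd-labelled spermatocyte replicate 1. Slides are not named in the files, so a slide block was not run. Signal over background limits dim probes: H2bc1 was above background on 7 of 44 arrays.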

Other observations

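The histone classes and the genes of the Y chromosome described here were chosen after their values were seen, and no test of their grouping was planned. Replication-type histones form the nucleosome core and its linker. In tagged spermatocytes 7 of 8 H3 genes rose, as did 5 of 12 H4 genes and 6 of 10 H2B genes, while 0 of 13 H2A genes and 0 of 3 H1 genes passed in limma's test. In tagged spermatids 7 H3 (median of the class 1.15), 9 H4 and 3 H2B genes rose, no H2A gene passed and 1 H1 gene fell. In kd-labelled spermatocytes 5 H2B genes rose, 1 H4 gene fell and no gene of the other classes passed. In kd-labelled spermatids 3 H2B genes rose and no other passed. H3c1 rose by 1.97 ± 0.26 (adjusted p = 4.09e-07) in tagged spermatocytes and 1.34 ± 0.26 (adjusted p = 1.00e-04) in tagged spermatids. No difference between the classes was tested. Probes of these near-identical genes may share signal, which was tested for H2bc1 alone (8 of 10 other H2B genes in the test of shared signal), so the member behind a change is uncertain.

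Of 15 measured genes on the Y chromosome 9 were higher in tagged spermatocytes and 6 in tagged spermatids, and none was lower. They included Sly, a multicopy regulator of sex chromosome genes in spermatids (1.32 ± 0.21, adjusted p = 2.56e-05 in spermatocytes; 1.34 ± 0.21, adjusted p = 4.57e-06 in spermatids), and Ssty1 (1.72 ± 0.30, adjusted p = 7.04e-05; 1.06 ± 0.30, adjusted p = 0.00882). In kd-labelled cells 0 of the 15 passed in either cell type. Among kd-labelled calls in either cell type, chromosome 13, which carries the TH2B gene, had a share of 6.34% of its tested genes called (26 of 410) and chromosome 7 one of 5.53% (55 of 994). Of the 26 calls 9 were histone genes, and without histone genes the share on chromosome 13 was 4.58%, below that on chromosome 7. The X chromosome had 0.771%.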
